A study of Homo sapiens with 11 samples.

How the data were processed

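RNA from HL-60 cells, a human promyelocytic leukaemia line, was measured on 11 Affymetrix arrays. All of the lines carried a GAL4-ER-VP16 fusion protein, per the labels. The EV line carried the fusion alone, and the other lines also carried a GATA2 construct that was wild type (WT), T354M, 355delT or L359V. Cells received 100 nM 4HT (4-hydroxytamoxifen, a ligand of the oestrogen receptor) for 24 h before RNA was purified. There were 3 arrays for 355delT and 2 for each of the other 4 groups, taken from the sample titles. Nothing in the labels says that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

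Both deposited tables hold log2 values summarised per probe set with RMA, per the submitters' processing notes, with no version stated. RMA corrects background, makes the distributions of the arrays alike and combines the probes of a probe set, so an overall rise or fall in RNA content cannot be seen. The deposited series value table holds log2 values after a further adjustment, and the other table holds them before it, per its deposited name. How the adjustment was made is not given in the sources used here. Between the tables all 3 arrays labelled 355delT moved together, with a lowest correlation of their shifts over probe sets of 0.974. They moved opposite to the other 8 arrays, with correlations from -0.922 to -0.853. The SD over probe sets of the gap between the 355delT mean and the mean of the other 8 arrays was 0.323 before the adjustment and 0.0492 after it. In 453 probe sets that gap was over 2-fold before, and in 0 after. For L359V against the remaining arrays, the same SD was 0.285 before and 0.198 after, with 297 and 71 probe sets over 2-fold. Deviations among the other 8 arrays shrank to 0.862 of their size, so their log2 changes were 1.16 times larger before the adjustment. Within the 3 arrays labelled 355delT, the slope of adjusted on pre-adjustment deviations was 1.11. It was pooled over probe sets, so the most variable ones weigh most in it. The SD over these arrays grew more in single genes such as HPGDS (0.234 before, 0.354 after) and GATA2 (0.078 and 0.118). No label gives an array date or batch, and the 355delT group and its possible batch cannot be told apart.

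The series value table was chosen for the reported values before the data were examined, as were the tests, the gene lists, the rule for named genes and most of the alternatives. Both tables are given for the named genes and called lists of comparisons with the arrays labelled 355delT. Every array had a median between 6.41 and 6.48 on the log2 scale in the series value table. Replicates of a group correlated at 0.994 to 0.996 over probe sets, and no pair of arrays was a duplicate.

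A linear model with 1 mean per group was fitted to all 11 arrays with limma 3.58.1 in R 4.3.3 and moderated with eBayes, with 6 residual and 3.29 prior degrees of freedom. The 8 comparisons were each GATA2 form against EV, each mutant against WT, and T354M against 355delT. P-values were adjusted by Benjamini-Hochberg over 33252 probe sets within each comparison, and a probe set counted as changed at an adjusted p under 0.05. Errors are standard errors (SE) of that fit, and changes are differences of log2 means. No comparison held 3 arrays in both groups, so regrouped arrays were not counted. On simulated data with 200 changed probe sets, the test of WT against EV recovered 32.5% of 1.5-fold changes, 90.5% of 2-fold changes and 99.5% of 4-fold changes. In the test of T354M against EV, 20% of 1.5-fold and 83.5% of 2-fold changes were recovered.

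Genes were named from the platform annotation supplied with the tables. It listed 1 gene for 19460 probe sets, several for 1754 and none for 12038. Of the first, 19429 matched a current RefSeq entry by Entrez identifier and 0 symbols had to be updated. Probe sets with several genes were counted but not named. Named genes were GATA2, the largest changes in each direction that passed with no overlap between the groups (10 against EV, 5 otherwise), and the largest passing members of the fixed lists (up to 15 against EV, 6 otherwise). Where fewer than 3 genes passed in a direction, the 3 largest changes at an unadjusted p under 0.05 were named as not having passed. Called lists were illustrated by their members with the largest changes.

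The 19 lists covered blood lineages (mast cell and basophil, eosinophil, megakaryocyte and platelet, erythroid, stem and progenitor, primary granule, late neutrophil, monocyte and macrophage, lymphoid), cell cycle G2/M, DNA replication in S phase, p53 targets, cholesterol synthesis, interferon response, unfolded protein and amino acid stress, immediate early genes, NF-kB cytokines, GATA family and partners, and hypoxia and glycolysis. They were tested with camera at a preset correlation of 0.01 between genes, on 1 probe set per gene for 18417 genes, with Benjamini-Hochberg adjustment over 152 tests. Some members, such as TPSAB1 and HBA1, had no probe set of their own and were not analysed here. The camera test made 55 calls, of which 0 held with an estimated correlation, and fry, which asks only whether a list moves on balance 1 way, made 17.

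The replicate numbers of the titles were checked for pairing. Residuals of arrays with the same number correlated at 0.219 to 0.342 among EV, WT, T354M and L359V, and at -0.138 to 0.0197 in the 8 pairs with 355delT. With 2 arrays in each of the first 4 groups both numbers of a pair of groups give the same correlation, so there were 6 distinct values. The numbers may therefore pair these 4 groups, which the labels do not state. A fit with the number as a block in those groups was added after the data were seen. The other alternatives were the pre-adjustment table, a replicate block over all arrays, both together, leaving out dim probe sets, quantile normalization, an intensity trend with a robust prior, only the compared groups, leaving out each array, leaving out all 355delT arrays, and only probe sets with a listed gene. The fits without the 355delT arrays, on listed probe sets, and with the 4-group block, and a split of the 2 EV arrays between comparisons, were chosen after seeing the data.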

Results

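Gene expression was measured in HL-60 cells that carried WT GATA2, 1 of the mutants T354M, 355delT and L359V, or no GATA2 construct (EV). GATA2 is a zinc finger transcription factor of blood stem cells, progenitors and mast cells. The design asked how the expression pattern produced by WT GATA2 compared with those of the mutants. The data were log2 probe set values of 11 arrays, 3 for 355delT and 2 for each other group, all from cells given 4HT. Unless stated otherwise, a change is a difference of group means on the log2 scale with its SE, n was 2 per group and 3 for 355delT, and adjusted p-values come from limma with Benjamini-Hochberg adjustment.

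GATA2 itself (probe set 8090469) was measured first, as a check of the labels. In the series value table its level was 9.86 and 9.95 in the EV arrays, 11.33 and 11.46 in WT, 11.09 and 11.32 in T354M, and 11.38 and 11.34 in L359V. Against EV, GATA2 was 2.81-fold higher in WT (SE 0.108 on the log2 scale, adjusted p = 0.000319), 2.46-fold higher in T354M (adjusted p = 0.0063) and 2.73-fold higher in L359V (adjusted p = 0.000324). The 3 arrays labelled 355delT held 10.81, 10.94 and 10.71, a log2 difference from EV of 0.91 (SE 0.0988, adjusted p = 0.0258). In the table before adjustment the same arrays held 10.11, 10.20 and 10.05 against 9.89 and 9.99 in EV, a difference of 0.18 that did not pass (SE 0.0994, adjusted p = 0.28). The GATA2 level therefore separated WT, T354M and L359V from EV, without telling these 3 forms apart, and did not separate the 355delT arrays from EV in both tables. The latter are called the arrays labelled 355delT throughout. The difference in T354M did not pass without EV replicate 1 or 2 (adjusted p = 0.0784 and 0.0581). That of the arrays labelled 355delT in the series value table passed only when a T354M array was left out, and otherwise had adjusted p-values up to 0.396, the highest without EV replicate 1. GATA2 differed from WT by -0.19 in T354M (adjusted p = 0.586) and by -0.04 in L359V (adjusted p = 0.895), neither beyond the spread between arrays. The probe set measures transcripts of the construct and of the cells' own gene together.

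**Figure D1:**
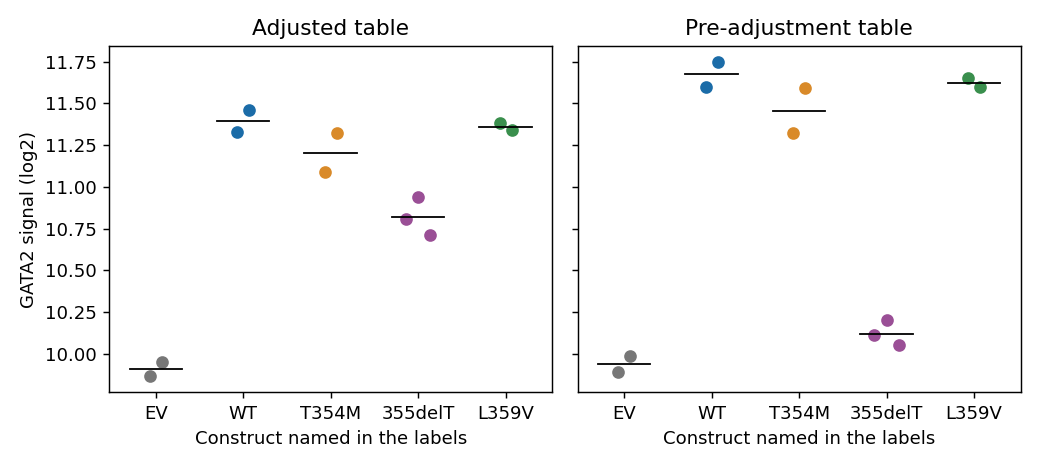
GATA2 signal (log2) of each array, by the construct named in the labels, in the adjusted and the pre-adjustment table; points are arrays and lines group means. The 3 arrays labelled 355delT lie from 10.71 to 10.94 in the adjusted table and from 10.05 to 10.20 before the adjustment, close to the EV arrays.

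WT GATA2 was set against EV to find the genes that differ with the normal protein. The constructs were in separate lines, and all arrays came from cells given 4HT. An effect of a construct and other differences between the lines therefore cannot be told apart in any comparison here. Mast cell genes were among those that rose most. HPGDS, the prostaglandin D synthase of blood cells, rose 13.6-fold (log2 change 3.77, SE 0.223, adjusted p = 0.000228), and CPA3, the carboxypeptidase of mast cell granules, rose 9.11-fold (3.19, SE 0.206, adjusted p = 0.000239). HDC, the enzyme that makes histamine, rose 3.67-fold, IL1RL1, a receptor of mast cells, 3.92-fold, and FCER1A, the IgE-binding chain of the high-affinity IgE receptor, 3.74-fold. GATA1, the related factor of erythroid cells and mast cells, rose 3.30-fold (SE 0.108, adjusted p = 0.000239). Of 19 measured members of the mast cell and basophil list 9 rose and 1, SIGLEC6, fell (log2 change -1.08, adjusted p = 0.0326), or 10 and 2 adjusted over the list alone. The list as a whole was higher (camera, adjusted p = 6.03e-09; adjusted p = 0.107 with an estimated correlation). KIT, the receptor for stem cell factor, stood at -0.78 and did not pass (adjusted p = 0.0591).

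Genes outside that list also rose in WT, though none as much as HPGDS or CPA3. TRAT1, an adaptor protein of T cell receptor signalling, rose 8.54-fold (SE 0.245, adjusted p = 0.000498), and HPGD, which inactivates prostaglandins, rose 6.04-fold. IL5RA, the alpha chain of an eosinophil cytokine receptor, rose 5.55-fold, SLFN5 5.52-fold, KIAA0040 4.68-fold, CDK15 4.33-fold and the myeloid integrin chain ITGAM 3.11-fold. The eosinophil list did not pass (adjusted p = 0.0909), with 2 of 14 members risen and 1 fallen. The cell cycle G2/M list was higher (adjusted p = 2.09e-08; adjusted p = 0.206 with an estimated correlation), with CENPE at 0.50, DLGAP5 at 0.43 and KIF23 at 0.38 as the 3 of 29 members that passed, or 15 adjusted over the list alone. The interferon list was also higher (adjusted p = 2.68e-05; adjusted p = 0.503 with an estimated correlation), with 2 of 30 members risen, RIGI by 0.69 and DDX60 by 0.56, or 9 adjusted over the list alone.

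Granule genes and several receptor and chemokine genes fell in WT. S100A8, a calcium-binding protein of neutrophils and monocytes, fell by 2.07 (SE 0.16, adjusted p = 0.000428), and the chitinase-like gene CHI3L1 fell by 1.75 (SE 0.125, adjusted p = 0.000319). The chemokine genes CCL1 and CCL2 fell by 2.51 and 1.88, the lectin receptor genes CLEC4E and CLEC5A by 1.87 and 1.57, and FCAR, a receptor for IgA, by 1.45. FFAR4, ROPN1L and CD180 fell by 1.67, 1.66 and 1.64. Of 19 measured primary granule genes 7 fell and 0 rose, or 8 adjusted over the list alone, including the protease gene CTSG (-1.17), the peroxidase gene MPO (-0.93) and CST7 (-1.18). That list was lower (adjusted p = 1.23e-06; adjusted p = 0.194 with an estimated correlation). The late neutrophil list was lower (adjusted p = 0.0111; adjusted p = 0.464 with an estimated correlation), with 4 of 31 members fallen and 2 risen, or 10 and 4 adjusted over the list alone. Cholesterol synthesis was lower with 1 of 19 members fallen, DHCR7 by 0.48, or 6 adjusted over the list alone (adjusted p = 0.000875; adjusted p = 0.478 with an estimated correlation). Hypoxia and glycolysis was lower with 3 of 26 fallen, among them the glucose transporter gene SLC2A1 by 0.59, and 1 risen, or 6 and 1 adjusted over the list alone (adjusted p = 0.0277; adjusted p = 0.598 with an estimated correlation).

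When 1 array was left out, calls ended for late neutrophil genes without EV replicate 1 (adjusted p = 0.0634), cholesterol synthesis without WT replicate 2 (0.0632), and hypoxia and glycolysis without EV replicate 2 or WT replicate 1 (0.077 and 0.137). The other lists did not pass for WT against EV. Their adjusted p-values were 0.572 for megakaryocyte and platelet, 0.564 for erythroid, 0.337 for stem and progenitor, 0.719 for monocyte and macrophage, and 0.376 for lymphoid genes. They were 0.401 for DNA replication in S phase, 0.952 for p53 targets, 0.912 for unfolded protein and amino acid stress, 0.289 for immediate early genes, 0.691 for NF-kB cytokines and 0.399 for GATA family and partners. The median and the mean of the erythroid, S phase, p53, unfolded protein and GATA family lists differed in sign. In all, 994 probe sets changed between WT and EV, 526 higher and 468 lower (836 and 845 with dim probe sets left out). Nearly 1 factor scaled these changes in the adjustment, so their signs were fixed between the tables. The count was 1806 in the table before adjustment, where all 994 were also called with the same sign, and 176, 171, 294 and 192 without EV replicate 1, EV replicate 2, WT replicate 1 and WT replicate 2. Of 27 named genes that passed, between 18 and 22 still passed without these arrays in turn.

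L359V, a substitution in the second zinc finger region, was set against EV in the same way. HPGDS rose 15.4-fold (log2 change 3.94, SE 0.223, adjusted p = 0.000185), GMPR, a purine nucleotide reductase, 8.70-fold (3.12, SE 0.243, adjusted p = 0.000378) and F5, coagulation factor V, 6.10-fold (2.61, SE 0.119, adjusted p = 8.52e-05). CRLF2, a cytokine receptor chain, rose 5.47-fold, HPGD 5.14-fold, SLFN5 5.13-fold, IL1RL1 4.73-fold, the inhibitor of helix-loop-helix factors ID3 4.33-fold, and GCSAML and CYP2B6 4.18-fold each. Of the 19 mast cell and basophil genes 6 rose and 1 fell, or 8 and 1 adjusted over the list alone (camera, adjusted p = 2.11e-05; adjusted p = 0.141 with an estimated correlation). CPA3 rose 3.79-fold, HDC 3.61-fold and FCER1A 3.19-fold. GATA1 stood at 0.15 and did not pass (SE 0.108, adjusted p = 0.548). ITGAM rose 4.13-fold, IL5RA 3.98-fold and the red cell membrane gene ERMAP 2.75-fold, while the eosinophil and erythroid lists did not pass (adjusted p = 0.949 and 0.952).

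Primary granule genes were lower in L359V than in EV, with 9 of 19 fallen and 0 risen, or 13 adjusted over the list alone (adjusted p = 2.94e-11; adjusted p = 0.113 with an estimated correlation). MPO fell by 1.82 (SE 0.143, adjusted p = 0.00039) and CTSG by 1.78 (SE 0.177, adjusted p = 0.00112). S100A8 fell by 2.53 (SE 0.16, adjusted p = 0.000251), and ANKRD22, CLEC4E, CCL1 and CD180 fell by 2.39, 2.10, 1.85 and 1.80. ROPN1L, CHI3L1 and the cyclin gene CCNA1 fell by 1.77, 1.74 and 1.66, and CEBPA, a transcription factor of granulocyte development, fell by 1.49 (SE 0.14, adjusted p = 0.00101). Of 31 late neutrophil genes 9 fell, among them HP (haptoglobin, -1.47), and 3 rose, or 11 and 5 adjusted over the list alone (adjusted p = 0.0131; adjusted p = 0.464 with an estimated correlation). Cholesterol synthesis was lower with 7 of 19 fallen, among them LSS and ACAT2 by 0.68 each, or 14 adjusted over the list alone (adjusted p = 1.59e-07; adjusted p = 0.265 with an estimated correlation).

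Unfolded protein and amino acid stress was lower in L359V with 5 of 30 members fallen and 1, ATF3, risen, or 9 and 1 adjusted over the list alone (adjusted p = 1.06e-06; adjusted p = 0.404 with an estimated correlation). The members that fell most were SLC7A11, a cystine transporter (-1.23), and PSAT1, an enzyme of serine synthesis (-0.74). Hypoxia and glycolysis was lower with 4 of 26 fallen and 1 risen, or 12 and 2 adjusted over the list alone (adjusted p = 0.000648; adjusted p = 0.436 with an estimated correlation), PDK1 and NDRG1 by 0.72 and 0.68. The interferon list was higher with 5 of 30 risen, IFIT5 by 1.02 and IRF9 by 0.79, or 13 adjusted over the list alone (adjusted p = 1.26e-05; adjusted p = 0.488 with an estimated correlation). Immediate early genes were higher with 3 of 26 risen, NR4A3 by 1.15, and 1, MYC, fallen by 0.90, or again 3 and 1 adjusted over the list alone (adjusted p = 0.0192; adjusted p = 0.783 with an estimated correlation). The late neutrophil call ended without EV replicate 1 (adjusted p = 0.0525), and the immediate early call without EV replicate 1 or L359V replicate 2 (0.195 and 0.264). In all, 1743 probe sets changed, 723 higher and 1020 lower. This balance turned round without EV replicate 2 (259 higher and 207 lower) and with only the 2 groups compared (128 and 105). All 1743 were also called among the 2866 of the table before adjustment, with the same sign, which the near-constant factor between the tables fixed. The count was 448, 466, 531 and 503 without EV replicate 1, EV replicate 2, L359V replicate 1 and L359V replicate 2, and 25 or 26 of 29 named genes still passed in each case.

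**Figure D2:**
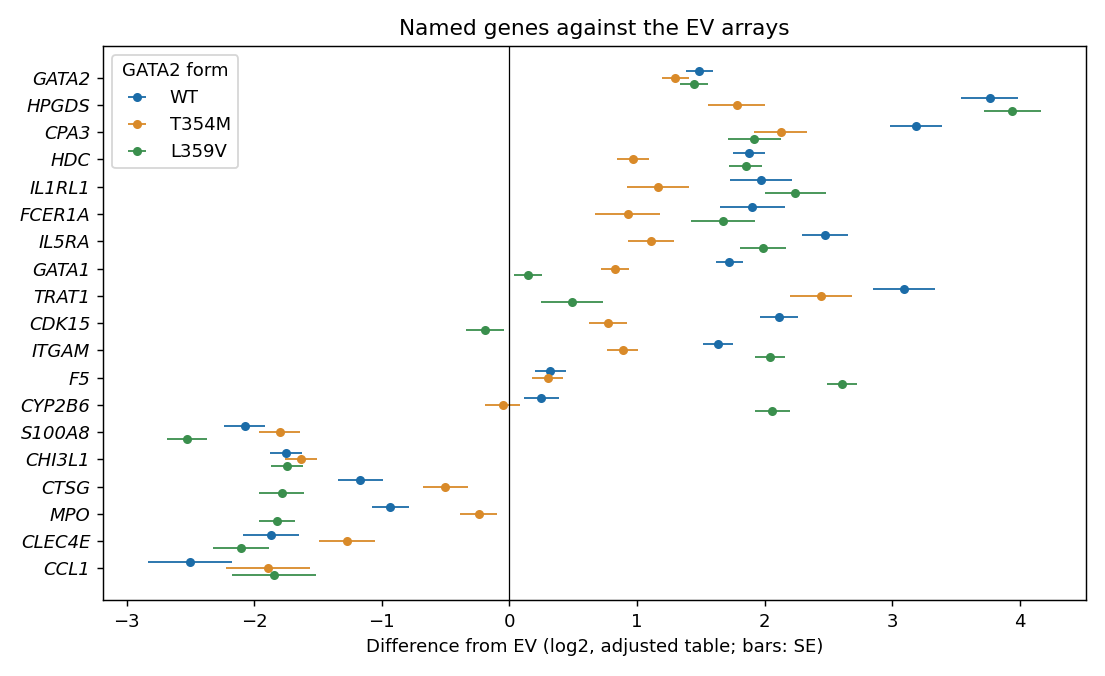
Differences from the EV arrays (log2, adjusted table) of named genes in WT, T354M and L359V; points are differences of group means and bars their SE. HPGDS lies at 3.77, 1.78 and 3.94 in the 3 forms, GATA1 at 1.72, 0.83 and 0.15, and F5 at 0.32, 0.30 and 2.61.

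The WT and L359V calls against EV overlapped. Both comparisons raised 263 probe sets and lowered 348, and 4 moved in opposite directions. Independent lists of these sizes would share 11.4 and 14.4. In simulations without any change, where both comparisons used the same simulated EV arrays, 0.02 calls were shared on average and at most 1 in 50 simulations. With nothing changed hardly any call can arise, so that count was fixed near 0 and is no reference for the overlap. The correlation of the changes over all probe sets was 0.597 (0.501 simulated), and their covariance was 0.0374 (0.0116 simulated), a difference of 0.0258. Genes are not independent replicates, and the shared EV arrays contribute to these values. Splitting the EV arrays between the comparisons removes that sharing but unbalances the replicate numbers. Residuals of equal numbers correlated at 0.219 to 0.342, which could lower the covariance, so 0 need not be its value for unchanged groups. With 1 EV array given to each comparison, a split chosen after seeing the data, WT had 171 or 176 calls and L359V 448 or 466. They then shared 56 higher and 45 lower in 1 arrangement (0.598 and 0.5 for independent lists, correlation 0.306, covariance 0.0234) and 51 and 45 in the other (0.771 and 0.479, correlation 0.275, covariance 0.0216).

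L359V was next compared with WT directly. F5 was 4.88-fold higher in L359V (log2 difference 2.29, SE 0.119, adjusted p = 0.000184), CD96, a receptor of T and natural killer cells, 4.11-fold higher (SE 0.222, adjusted p = 0.00582), and the prostaglandin transporter gene SLCO2A1 3.73-fold higher (SE 0.308, adjusted p = 0.0286). GMPR and CYP2B6 were 3.69-fold and 3.51-fold higher, and FPR1, a receptor for formylated peptides, 2.53-fold higher. TRAT1 was lower by 6.08-fold (log2 difference -2.60, SE 0.245, adjusted p = 0.00296), CDK15 by 4.94-fold and the lymphocyte adaptor gene LAX1 by 4.11-fold. The receptor genes GPR34 and GPR65 were 3.68-fold and 3.04-fold lower, and GATA1 was 2.99-fold lower (SE 0.108, adjusted p = 0.000872). SLC7A11, CSF3R (the receptor for G-CSF), CPA3 and TNFAIP3 (an inhibitor of NF-kB signalling) were lower by 2.91-fold, 2.71-fold, 2.41-fold and 2.26-fold. HPGDS and HDC did not pass (0.18 and -0.03, adjusted p = 0.76 and 0.946).

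Of the lists, 8 were lower in L359V than in WT and 0 higher. Unfolded protein and amino acid stress had 3 of 30 members lower, SLC7A11, CEBPB and EDEM1, or 7 lower and 1 higher adjusted over the list alone (adjusted p = 5.78e-09; adjusted p = 0.265 with an estimated correlation). Primary granule genes had 2 of 19 lower, MPO by 0.89 and RAB44 by 0.84, or 5 adjusted over the list alone (adjusted p = 0.000166; adjusted p = 0.265 with an estimated correlation). Cell cycle G2/M had 0 of 29 members past the threshold, or 7 lower adjusted over the list alone (adjusted p = 3.01e-06; adjusted p = 0.265 with an estimated correlation). Cholesterol synthesis and DNA replication also had 0 members past the threshold, or 2 and 0 lower adjusted over the list alone (adjusted p = 0.000769 and 0.0365; adjusted p = 0.478 and 0.75 with an estimated correlation). The eosinophil list had 1 of 14 higher, PIK3R6, against its direction, or 2 higher and 6 lower adjusted over the list alone (adjusted p = 0.00598; adjusted p = 0.265 with an estimated correlation). GATA family and partners had 1 of 20 lower, GATA1, or 5 adjusted over the list alone (adjusted p = 0.025; adjusted p = 0.478 with an estimated correlation). The mast cell and basophil list had 2 of 19 lower, GATA1 and CPA3, or 5 adjusted over the list alone, and its call (adjusted p = 0.0392; adjusted p = 0.414 with an estimated correlation) ended in the table before adjustment (adjusted p = 0.0663), though its median was -0.0308 there and -0.0264 in the series value table, and with a replicate block over all arrays (adjusted p = 0.0764). When 1 array was left out, the mast cell call ended without WT replicate 2, L359V replicate 2, 355delT replicate 2 or 355delT replicate 3 (adjusted p = 0.258, 0.0996, 0.0821 and 0.0572), and the GATA family call without L359V replicate 2 or 355delT replicate 2 (0.108 and 0.0621). So did DNA replication without WT replicate 2 or L359V replicate 1 (0.203 and 0.289), cholesterol synthesis without WT replicate 1 (0.0834) and the eosinophil list without L359V replicate 2 (0.061). In all, 281 probe sets differed, 92 higher and 189 lower in L359V, and all 281 were also called among the 741 of that table. The count was 150 without the 355delT arrays, 167 without either EV array, and 56, 27, 41 and 53 without L359V replicate 1, L359V replicate 2, WT replicate 1 and WT replicate 2, where 11, 8, 9 and 11 of the 16 named genes still passed.

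T354M, a mutation found in families with myelodysplasia and acute leukaemia, was compared with EV. TRAT1 rose 5.44-fold (log2 change 2.44, SE 0.245, adjusted p = 0.0108), CPA3 4.37-fold (2.13, SE 0.206, adjusted p = 0.0101) and HPGDS 3.44-fold (1.78, SE 0.223, adjusted p = 0.0349). CYP17A1, an enzyme of steroid synthesis, rose 2.95-fold, the lymphoid factor gene IKZF3 2.29-fold, the fatty acid transport gene SLC27A2 2.23-fold, GPR65 2.15-fold, MS4A6A 2.04-fold and NDFIP2 2.01-fold. HDC, ITGAM and GATA1 rose 1.96-fold, 1.85-fold and 1.77-fold. S100A8 fell by 1.80 (SE 0.16, adjusted p = 0.00675), CHI3L1 by 1.63 (SE 0.125, adjusted p = 0.0046) and NRP1, a semaphorin receptor gene, by 1.30. S100Z, FCAR, ERAP2, MYOF, MTSS2, BST1 and GLG1 fell by 0.97, 0.93, 0.81, 0.76, 0.72, 0.61 and 0.59.

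The mast cell and basophil list was higher in T354M, with 4 of 19 risen (CPA3, HPGDS, HDC and GATA1), or 7 risen and 2 fallen adjusted over the list alone (camera, adjusted p = 1.95e-07; adjusted p = 0.107 with an estimated correlation). The eosinophil list was higher with 0 of 14 members past the threshold, or 6 risen and 1 fallen adjusted over the list alone (adjusted p = 0.000275; adjusted p = 0.194 with an estimated correlation), EPX standing at 1.93 and IL5RA at 1.11. Cell cycle G2/M and unfolded protein and amino acid stress were higher with 0 members past the threshold in either count (adjusted p = 0.00542 and 0.00243; adjusted p = 0.503 and 0.598 with an estimated correlation). The late neutrophil list was lower with 2 of 31 fallen, S100A8 and CHI3L1, and 1, ITGAM, risen, or 8 and 2 adjusted over the list alone (adjusted p = 0.0126; adjusted p = 0.464 with an estimated correlation), a call that ended with a replicate block over all arrays (adjusted p = 0.0568). It also ended without EV replicate 1 or T354M replicate 1 (0.158 and 0.0583), as did the G2/M call without EV replicate 1 (0.0964) and the unfolded protein call without T354M replicate 2 (0.392). The primary granule list did not pass (adjusted p = 0.377), nor did MPO at -0.24 or CTSG at -0.50. In all, 40 probe sets changed, 27 higher and 13 lower (15 and 15 with a replicate block over all arrays, 3 and 7 without T354M replicate 2). Of these, 39 were also called in WT, 27 higher and 12 lower in both, where independent lists would share 0.427 and 0.183. Simulated unchanged groups shared 0.02 on average, again a count fixed near 0. The correlation of the T354M and WT changes was 0.588 (0.501 simulated) and their covariance 0.0256 (0.0116 simulated), a difference of 0.014. Splitting the EV arrays again unbalanced the replicate numbers. With 1 EV array given to each comparison the correlation was 0.163 or 0.202 and the covariance 0.00986 or 0.0115, and limma called 0 probe sets in T354M (2099 or 1457 at an unadjusted p under 0.05), so shared calls could not be counted in that split. The planned replicate block over all arrays gave 30, of which 21 were among the 40, and 9 of the 23 named genes lost the call there, among them MS4A6A, GPR65, BST1, CYP17A1 and HDC (adjusted p = 0.107, 0.105, 0.0938, 0.0782 and 0.0649). The count was 73 before the adjustment, 65 with the block in the 4 groups other than 355delT, which was chosen after seeing the data, 9 without the 355delT arrays, where 8 of 23 named genes still passed, and 0 without either EV array. It was 11 and 10 without T354M replicates 1 and 2, 11 without either WT array, 14 without either L359V array, and 20, 18 and 19 without 355delT replicates 1, 2 and 3.

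T354M was also compared with WT directly. HPGDS was 3.96-fold lower in T354M (log2 difference -1.98, SE 0.223, adjusted p = 0.0272), and IL5RA and RGS13, a regulator of G protein signalling, were 2.57-fold lower each (SE 0.18 and 0.12, adjusted p = 0.0454 and 0.016). The desmosomal gene DSC1 was 2.56-fold lower, CDK15 2.53-fold, MITF, a transcription factor of mast cells and melanocytes, 2.30-fold (SE 0.0951, adjusted p = 0.012), and GATA1 1.86-fold. TMEM65 was the gene that passed as higher, by 1.66-fold (adjusted p = 0.0272). CHAC1, CST7 and RNASE2CP had larger differences, of 1.19, 1.06 and 0.99, that did not pass (adjusted p = 0.296, 0.142 and 0.0792). CST7 passed with the numbers as a block in the 4 groups other than 355delT (adjusted p = 0.039), a fit chosen after seeing the data, and not with the planned replicate block over all arrays (adjusted p = 0.0711).

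The mast cell and basophil list was lower in T354M than in WT, with 3 of 19 lower (HPGDS, MITF and GATA1), or 8 adjusted over the list alone (camera, adjusted p = 1.71e-06; adjusted p = 0.113 with an estimated correlation). Primary granule genes were higher with 0 of 19 past the threshold, or 11 adjusted over the list alone (adjusted p = 2.09e-08; adjusted p = 0.148 with an estimated correlation). Interferon and G2/M genes were lower with 0 members past the threshold, or 8 and 4 adjusted over the list alone (adjusted p = 9.13e-07 and 1.33e-06; adjusted p = 0.464 and 0.265 with an estimated correlation). DNA replication was lower, and cholesterol synthesis and unfolded protein stress were higher, with 0 members past the threshold, or 0, 1 and 0 adjusted over the list alone (adjusted p = 0.00598, 0.00259 and 0.0253; adjusted p = 0.682, 0.513 and 0.716 with an estimated correlation). The unfolded protein call ended with a replicate block over all arrays (adjusted p = 0.0639) and without WT replicate 2, T354M replicate 2 or 355delT replicate 2 (0.57, 0.529 and 0.0631). The cholesterol call ended without WT replicate 2 or T354M replicate 1 (0.195 and 0.0737), and the DNA replication call without T354M replicate 1 (0.213). In all, 26 probe sets differed, 1 higher and 25 lower in T354M. All were also called among the 217 of the table before adjustment, of which 73 were higher and 144 lower. The balance was 82 higher and 141 lower with dim probe sets left out, and 1 and 21 with the replicate block over all arrays. The planned replicate block over all arrays gave 22, of which 12 were among the 26, and DSC1, TMEM65 and IL5RA lost the call there (adjusted p = 0.0702, 0.0574 and 0.0543). The count was 79 with the numbers as a block in the 4 groups other than 355delT and 0 without the 355delT arrays, where 0 of 8 named genes still passed. It was 0 without T354M replicate 1, T354M replicate 2 or WT replicate 2, 6 without WT replicate 1, 4 without either EV array, 2 without either L359V array, and 10, 26 and 14 without the 355delT arrays in turn.

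355delT, a deletion that has also been found in such families, was compared with EV, and most of the rises here depend on which deposited table is read. In the series value table HPGDS was 3.77-fold higher in the arrays labelled 355delT (log2 difference 1.92, SE 0.203, adjusted p = 0.0258), and before the adjustment it stood at -0.51 (SE 0.188, adjusted p = 0.113). HDC stood at 0.94 and -0.34, ITGAM at 0.87 and -0.62, and EEIG2 at 0.83 and -0.20 in the adjusted and the pre-adjustment table. USP53 stood at 0.86 and -0.01, TESPA1 at 0.83 and -0.04, MGAM2 at 0.81 and -0.28, SLC27A2 at 0.80 and -0.12, and NDFIP2 at 0.86 and 0.32. Before the adjustment ITGAM passed as lower (adjusted p = 0.00901). None of the other genes named so far in this comparison passed there (lowest adjusted p = 0.0572, for NDFIP2). Genes that were lower were lower in both tables, but this is no separate support. The adjustment moved the 355delT mean close to that of the other 8 arrays, and WT, T354M and L359V also held less of these genes than EV. A fall in the series value table was therefore to be found whatever 355delT does, and the same limit holds for the lists of this comparison. S100A8 stood at -1.45 and -0.88, CHI3L1 at -1.19 and -0.87, FCAR at -0.90 and -0.66, IL6R, the interleukin 6 receptor gene, at -0.77 and -0.66, and MTSS2 at -0.62 and -0.56, each with an adjusted p under the threshold in both (highest 0.0385 for IL6R in the adjusted table and 0.00542 for S100A8 before the adjustment).

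**Figure D3:**
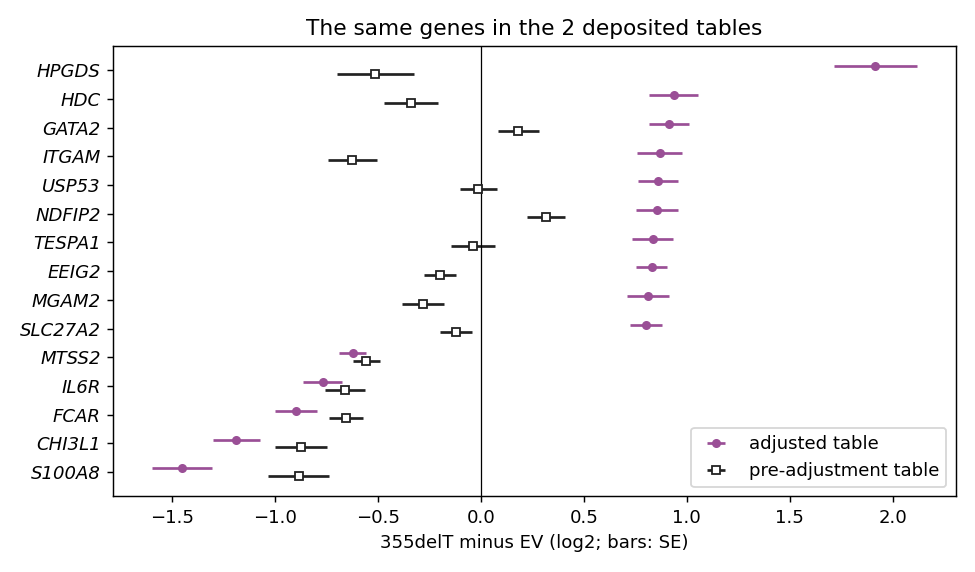
Differences between the arrays labelled 355delT and the EV arrays (log2) for the same genes in the adjusted and the pre-adjustment table; points are differences of group means and bars their SE. HPGDS lies at 1.92 in the adjusted table and at -0.51 before the adjustment, while S100A8 lies below 0 in both, at -1.45 and -0.88.

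The mast cell and basophil list was higher in the arrays labelled 355delT with 2 of 19 risen, HPGDS and HDC, or 7 risen and 1 fallen adjusted over the list alone (camera, adjusted p = 1.16e-07; adjusted p = 0.107 with an estimated correlation). Before the adjustment the same list was lower, with 5 fallen and 0 risen (adjusted p = 0.0059; adjusted p = 0.351 with an estimated correlation). Late neutrophil genes were lower before and after the adjustment. After it 2 of 31 had fallen, S100A8 and CHI3L1, and 1 had risen, or 7 and 2 adjusted over the list alone (adjusted p = 0.000366; adjusted p = 0.265 with an estimated correlation), and before the adjustment 9 had fallen and 0 risen (adjusted p = 0.00095; adjusted p = 0.351 with an estimated correlation). G2/M genes were higher and cholesterol synthesis lower before and after the adjustment. After it 0 members of either passed, or 0 and 4 adjusted over the list alone (adjusted p = 7.63e-07 and 1.26e-06; adjusted p = 0.265 and 0.285 with an estimated correlation). Before the adjustment 12 G2/M genes had risen and 1 fallen, and 7 cholesterol synthesis genes had fallen (adjusted p = 1.86e-06 and 0.00207; adjusted p = 0.27 and 0.538 with an estimated correlation). Primary granule genes were lower, interferon genes higher, and hypoxia and glycolysis genes lower in the series value table, with 0 members past the threshold, or 6, 0 and 0 adjusted over the list alone (adjusted p = 1e-06, 0.00343 and 0.00243; adjusted p = 0.194, 0.682 and 0.478 with an estimated correlation). Before the adjustment the primary granule and interferon medians had the opposite sign (0.144 against -0.178, and -0.1 against 0.0861), and neither list passed (adjusted p = 0.356 and 0.187). The hypoxia median was -0.108 before and -0.0925 after, so its call ended (adjusted p = 0.192) without a smaller median, and it also ended with the numbers as a block in the 4 groups other than 355delT (adjusted p = 0.0826). In all, 19 probe sets changed in the series value table, 14 higher and 5 lower, and 4429 before the adjustment, 2074 higher and 2355 lower. Of the 19, 6 were also called with the same sign in the latter and 9 had the opposite sign. The interferon call also ended without EV replicate 1 or 355delT replicate 2 (adjusted p = 0.0525 and 0.121). The count was 20 with the numbers as a block in the 4 groups other than 355delT, where NDFIP2, IL6R and MGAM2 lost the call (adjusted p = 0.0542, 0.0567 and 0.0591). A replicate block over all arrays gave 0, with 2150 at an unadjusted p under 0.05. Without T354M replicate 1 or 2 the count was 10, without 355delT replicate 1 it was 2, without L359V replicate 1 or 2 it was 1, and without any of the other 6 arrays it was 0.

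Against WT, directions in the arrays labelled 355delT were the same in both tables for the genes that passed, and the sizes differed. The shared directions are no separate support. After the adjustment the 355delT mean lay close to that of the other 8 arrays, so genes high in WT came out lower whatever 355delT does. This limit also holds for the lists and counts of this comparison. HPGDS was 3.61-fold lower (log2 difference -1.85, SE 0.203, adjusted p = 0.021) in the series value table and 29.9-fold lower before the adjustment (-4.90, SE 0.188). CPA3 was 3.59-fold and 30.2-fold lower (adjusted p = 0.0164 and 8.9e-06). TRAT1 stood at -1.76 and -3.15, CDK15 at -1.60 and -2.81, IL5RA at -1.31 and -2.91, GATA1 at -1.15 and -1.99, HDC at -0.94 and -2.53, and ITGAM at -0.77 and -2.53. MTSS2 and TMEM65 were higher, at 0.59 and 0.58 in the series value table and 0.86 and 1.06 before the adjustment. CCL1, CCL2 and FFAR4 stood at 1.06, 0.91 and 0.89 and did not pass in the series value table (adjusted p = 0.482, 0.746 and 0.65), though CCL1 and FFAR4 passed with the numbers as a block in the 4 groups other than 355delT (adjusted p = 0.0271 each). That fit was chosen after seeing the data, and it lost ITGAM, TRAT1 and TMEM65 (adjusted p = 0.0519, 0.0647 and 0.0725), while the planned replicate block over all arrays did not call CCL1 or FFAR4 (0.225 and 0.115). Before the adjustment they stood at 1.88, 1.64 and 1.04 (adjusted p = 0.00607, 0.0174 and 0.065). GATA2 itself stood at -0.58 (adjusted p = 0.111) and at -1.55 before the adjustment (adjusted p = 4.99e-05).

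The mast cell and basophil list was lower than in WT with 5 of 19 lower, or 9 adjusted over the list alone (camera, adjusted p = 1.41e-11; adjusted p = 0.107 with an estimated correlation). Before the adjustment 11 were lower and 1 higher (adjusted p = 3.79e-08; adjusted p = 0.208 with an estimated correlation). The eosinophil list was lower with 1 of 14 lower, IL5RA, in both counts (adjusted p = 0.0136; adjusted p = 0.309 with an estimated correlation), and with 7 lower and 1 higher before the adjustment (adjusted p = 0.00353; adjusted p = 0.27 with an estimated correlation). Primary granule genes were higher and interferon genes lower with 0 members past the threshold, or 3 and 0 adjusted over the list alone (adjusted p = 2.87e-05 and 2.3e-05; adjusted p = 0.265 and 0.503 with an estimated correlation). Before the adjustment 10 primary granule genes were higher and 1 lower, and 12 interferon genes lower (adjusted p = 1.09e-05 and 4.21e-05; adjusted p = 0.27 and 0.553 with an estimated correlation). G2/M genes were lower with 0 members past the threshold in either count (adjusted p = 1.45e-06; adjusted p = 0.265 with an estimated correlation), a call that ended before the adjustment (adjusted p = 0.854), where the median was 0.0313 against -0.108. The eosinophil call ended without WT replicate 1 (adjusted p = 0.0904), and the primary granule and interferon calls without WT replicate 2 (0.0665 and 0.132). In all, 33 probe sets differed, 2 higher and 31 lower, and all 33 were also called with the same sign among the 6150 of the table before adjustment. The count was 21 with the block in the 4 groups other than 355delT and 0 with a replicate block over all arrays, where 2278 had an unadjusted p under 0.05. It was 0 without WT replicate 1 or 2, 4, 17 and 4 without 355delT replicates 1, 2 and 3, 15 without either EV array, 10 without either L359V array and 11 without either T354M array.

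Between T354M and the arrays labelled 355delT, limma called 0 probe sets in the series value table, with 563 at an unadjusted p under 0.05. Before the adjustment it called 5219, with 9803 at an unadjusted p under 0.05. GATA2 stood at 0.39 in the series value table (SE 0.0988), where it did not pass, and at 1.33 before the adjustment (SE 0.0994, adjusted p = 0.000255). The largest differences with separate values were in EPX, eosinophil peroxidase (1.52, SE 0.465), TRAT1 (1.11) and BBOX1 (0.94) on the higher side and in SLCO2A1 (-0.69), TMEM117 (-0.61) and ITGA6 (-0.59) on the lower side, and none passed (adjusted p = 1 for each). Before the adjustment EPX, TRAT1 and BBOX1 stood at 2.26, 2.39 and 2.08 (adjusted p = 0.0235, 0.000374 and 0.00978) and TMEM117 and ITGA6 at -0.61 and -0.56 (adjusted p = 0.0114 and 0.0167), while SLCO2A1 stood at 0.32 and did not pass (adjusted p = 0.577). Lists with small mean shifts were still called. Eosinophil, primary granule, cholesterol synthesis, unfolded protein stress, and GATA family lists were higher in T354M (adjusted p = 1.23e-05, 2.65e-07, 4.16e-06, 0.00259 and 0.00259; adjusted p = 0.141, 0.194, 0.315, 0.598 and 0.345 with an estimated correlation). Interferon, DNA replication and G2/M lists were lower (adjusted p = 0.000199, 0.00177 and 0.0212; adjusted p = 0.576, 0.598 and 0.598 with an estimated correlation), the G2/M call ending with the numbers as a block in the 4 groups other than 355delT (adjusted p = 0.0539). Without T354M replicate 2 the unfolded protein mean turned to -0.00512 (adjusted p = 0.91), and without 355delT replicate 1 its call ended (0.0622). Without T354M replicate 1 the interferon mean was 0.00575 (0.988), and the DNA replication and G2/M calls ended (0.609 and 0.0737). Without T354M replicate 2 the G2/M and GATA family calls ended (0.179 and 0.171), and without 355delT replicate 2 the G2/M, DNA replication and GATA family calls (0.502, 0.0745 and 0.206). In the series value table no member of these 8 lists passed the threshold over all probe sets, and 0 passed adjusted over the list alone. Before the adjustment the primary granule, interferon and unfolded protein shifts had the opposite sign (adjusted p = 0.132, 0.166 and 4.62e-06; adjusted p = 0.746, 0.874 and 0.484 with an estimated correlation). The eosinophil, cholesterol synthesis, GATA family, DNA replication and G2/M shifts kept their sign there (adjusted p = 7.68e-05, 0.0222, 0.0804, 0.00601 and 0.00136; adjusted p = 0.208, 0.722, 0.557, 0.73 and 0.484 with an estimated correlation). With the numbers as a block in the 4 groups other than 355delT, a fit chosen after seeing the data, 1 probe set was called, EPX (adjusted p = 0.0339). The planned replicate block over all arrays called 0 in the series value table (adjusted p = 0.999 for EPX). The arrays labelled 355delT cannot be told apart from a batch of their own in any of these values.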

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

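All tests of explanations in this part were chosen after the results were seen. Probe sets for which the annotation lists no gene enter the counts of changed probe sets above but name no gene. Of these 12038, 60 rose in WT against EV and 68 in L359V against EV, above the level in the EV arrays. Among all 33252 probe sets, 526 and 723 rose, so those without a listed gene rose less often than the others. The largest rises were in probe sets 8163000 (1.96, SE 0.235, adjusted p = 0.00401) and 7896709 (1.71, adjusted p = 0.00616) in WT, and 8139128 (1.33, adjusted p = 0.0126) and 7894327 (1.22, adjusted p = 0.0318) in L359V. What these probe sets measure is not given in the sources used here, and no explanation was tested.

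In the series value table, where the arrays labelled 355delT held higher HPGDS, HDC and GATA2 than EV, centring the pre-adjustment 355delT arrays on the mean of the other 8 arrays gave differences from EV that correlated at 0.939 over probe sets with those of the series value table, against 0.499 without centring. Since the adjustment had closed that gap (SD 0.0492, from 0.323), this correlation follows from it and is no separate test. With so small a gap, the 355delT minus EV differences of the series value table lay close to those between the mean of the other 8 arrays and EV. Most of those 8 carried GATA2, so such rises came with the adjustment and say little about 355delT itself. The biological alternative, a weaker response of the same genes, was measured before the adjustment as the median over the 723 probe sets that rose in L359V. It was -0.0806 (95% interval over probe sets, not over replicates, -0.116 to -0.0486), but over the WT-raised probe sets it was 0.0444. A weaker response and a batch of the 355delT arrays cannot be told apart here, since every 355delT array would belong to that batch. Before the adjustment, probe sets without a listed gene passed at 0.596 of the rate of those with a listed gene, against at most 0.279 in the other comparisons with EV, as a batch could produce, and an effect of 355delT itself stays open.

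The genes that differed between L359V and WT were weighed next. GATA2 transcript differed by -0.0408 (95% interval -0.284 to 0.203), and a difference of level within that interval stays open. Of 91 probe sets that differed and also responded in T354M at an unadjusted p under 0.05, 71 differed opposite to that response, as a lower level could produce, and 20 along it, which leaves the share in doubt. Before the adjustment and without the 355delT arrays, 281 of the 281 probe sets kept their sign and an unadjusted p under 0.05 (133 passed at an adjusted p), but the adjustment scaled these differences by nearly 1 factor, so that outcome was fixed and decides nothing about the adjustment. That the substitution changes which genes GATA2 acts on, and differences between the lines other than the construct, stay open as untested.

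Median changes over the probe sets that rose or fell in L359V were smaller in T354M than in WT. Not every gene followed the median. Mean levels in EV, WT and T354M were 7.09, 8.64 and 8.65 for CYP17A1, and 7.08, 5.95 and 5.78 for NRP1. Over the 723 probe sets that rose in L359V, the ratio of the T354M median to the WT median was 0.423 (95% interval over probe sets 0.382 to 0.471). The same ratio for GATA2 itself was 0.873, and in these arrays the gap ran against a response in proportion to transcript level. Intervals of this ratio treat probe sets of the same arrays as independent and leave out the spread between replicates. The GATA2 ratio has no interval, so how far the gap exceeds that spread was not measured. The ratio was 0.42 (0.38 to 0.463) before the adjustment without the 355delT arrays, but nearly 1 factor scaled both changes, so the ratio could not move and this decides nothing about the adjustment. All 3 sets of changes share the EV arrays, and protein level was not measured, so a lower amount or activity of the T354M protein and a response that is not proportional may each be the source.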

How the results depend on the processing

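The fits without all 355delT arrays, with the block for 4 groups and on probe sets with a listed gene were chosen after seeing the data, and the other alternatives before. For comparisons of EV, WT, T354M and L359V, values of named genes kept direction and side of the threshold in 1091 cases, lost the call in 136, gained it in 7 and reversed in 1 over the alternatives other than leaving out 1 array. Lists kept theirs in 272 cases and lost the call in 78. With the arrays labelled 355delT, genes kept theirs in 226 cases, lost the call in 56, gained it in 35 and reversed in 26, and lists kept theirs in 132, lost the call in 49 and reversed in 19. Lists were not recomputed with the trend prior, without the 355delT arrays or on listed probe sets alone. Camera with an estimated correlation called 0 lists and fry 17, against 55. The cause was not tested for any difference below unless one is given.

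Among EV, WT, T354M and L359V the changes were 1.16 times larger before the adjustment by nearly 1 factor. That their signs were the same there thus says nothing about stability. The factor also scaled the spread within these groups, so it cannot by itself raise the counts. Without the 355delT arrays, T354M against EV, T354M against WT and L359V against WT gave nearly the same counts in both tables. In these comparisons the larger counts before the adjustment came with the spread within the 355delT arrays, which enters the shared residual. In the pre-adjustment table without a block the counts were 1806 for WT, 73 for T354M, 4429 for 355delT and 2866 for L359V against EV, 217, 6150 and 741 for T354M, 355delT and L359V against WT, and 5219 for T354M against 355delT. GATA2 in the arrays labelled 355delT stood at 0.18 against EV (adjusted p = 0.28). Reversed against EV in those arrays were HPGDS (-0.51), HDC (-0.34), ITGAM (-0.62), USP53 (-0.01131), TESPA1 (-0.03725), EEIG2 (-0.20), MGAM2 (-0.28) and SLC27A2 (-0.12), and the means of the mast cell (-0.364), primary granule (0.109) and interferon lists (-0.129). Reversed for T354M against 355delT were SLCO2A1 (0.32) and the primary granule (-0.182), interferon (0.119) and unfolded protein lists (-0.455).

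In the pre-adjustment table with a replicate block the counts were 1694 for WT, 3631 for 355delT and 2679 for L359V against EV, 121, 5344 and 512 for T354M, 355delT and L359V against WT, and 4492 for T354M against 355delT. GATA2 stood at 0.22 (adjusted p = 0.197) in the arrays labelled 355delT, HPGDS at -0.52, HDC at -0.31, ITGAM at -0.65, USP53 at -0.01016, TESPA1 at -0.06181, EEIG2 at -0.18, MGAM2 at -0.24 and SLC27A2 at -0.09626. The mast cell, primary granule and interferon means were -0.359, 0.104 and -0.12, and G2/M against WT reversed to 0.0154. For T354M against 355delT, SLCO2A1 stood at 0.31 and the primary granule, interferon and unfolded protein lists at -0.176, 0.11 and -0.452. In the series value table with a replicate block, 355delT against EV and against WT gave 0 each by limma (2150 and 2278 at an unadjusted p under 0.05), and GATA2 in those arrays stood at 0.97 (adjusted p = 0.0748).

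With a replicate block for 4 groups in the series value table, T354M gave 65 against EV and 79 against WT, 355delT against WT gave 21 and T354M against 355delT gave 1. In the pre-adjustment table with that replicate block the counts were 2671 for WT, 166 for T354M, 5543 for 355delT and 3814 for L359V against EV, 610, 7537 and 1262 for T354M, 355delT and L359V against WT, and 6838 for T354M against 355delT. GATA2 stood at 0.24 (adjusted p = 0.116) in the arrays labelled 355delT, HPGDS at -0.42, HDC at -0.24, ITGAM at -0.53, USP53 at -0.06522, EEIG2 at -0.19, MGAM2 at -0.35 and SLC27A2 at -0.13, and the mast cell, primary granule and interferon means were -0.308, 0.0792 and -0.0221. For T354M against 355delT, SLCO2A1 stood at 0.003435 and the primary granule, interferon and unfolded protein lists at -0.152, 0.0123 and -0.477.

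Without all 355delT arrays the series value table gave 9 for T354M against EV, 0 for T354M against WT and 150 for L359V against WT, and the values before the adjustment gave 9, 0 and 151. With only the 2 groups compared, WT, T354M, 355delT and L359V against EV gave 103, 0, 0 and 233, and T354M, 355delT and L359V against WT 0, 5 and 5. GATA2 against EV then stood at 1.30 in T354M (adjusted p = 0.376) and 0.91 in the arrays labelled 355delT (adjusted p = 0.141). Both settings leave fewer residual degrees of freedom. With dim probe sets left out, WT, 355delT and L359V against EV gave 1681, 41 and 2620, and T354M, 355delT and L359V against WT 223, 70 and 562. On probe sets with a listed gene, WT, T354M and 355delT against EV gave 1615, 107 and 75, and the mutants against WT 270, 109 and 527 in the same order. Fewer probe sets were tested in both. With the trend prior 355delT against EV gave 33, and T354M, 355delT and L359V against WT gave 107, 60 and 447. Quantile normalization put GATA2 in L359V against WT at 0.03875 (adjusted p = 0.919).

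Leaving out 1 array at a time leaves its group with 1 array, or 2 for 355delT, and a lone array is assumed to vary like the other groups. The counts then ranged from 171 to 1091 for WT, 0 to 20 for T354M, 0 to 10 for 355delT and 448 to 1931 for L359V against EV, 0 to 26, 0 to 17 and 27 to 288 for T354M, 355delT and L359V against WT, and 0 to 0 for T354M against 355delT. Called lists ranged from 48 to 61. GATA2 against EV ranged from 1.18 to 1.42 in T354M (adjusted p = 0.0125 to 0.0784) and from 0.85 to 0.97 in the arrays labelled 355delT (0.0401 to 0.396). In L359V against WT it ranged from -0.1045 to 0.02292, above 0 without WT replicate 2. The unfolded protein mean for T354M against 355delT ranged from -0.00512 to 0.212. The interferon mean of that comparison was 0.00575 without T354M replicate 1, though the list was called lower. Its direction in the camera test, by which reversed lists are counted, stayed lower. For each comparison most of the arrays left out belonged to neither group, where the difference of means could not change. The tallies below therefore overstate how stable the directions were. Named genes of comparisons without 355delT kept the call or its absence in 855 cases, lost the call in 299 and reversed in 1, and their lists kept theirs in 358 and lost it in 27. With 355delT, genes kept theirs in 179 cases and lost the call in 206, and lists kept theirs in 205, lost it in 14 and reversed in 1.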

Other observations

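The genes of this paragraph are transcription factors chosen after their values were seen, and they stand for no list. The fixed list of GATA family and partners did not pass in WT or L359V against EV (adjusted p = 0.399 and 0.632). CEBPA fell by 0.88 in WT and by 1.49 in L359V against EV (SE 0.14, adjusted p = 0.0132 and 0.00101), SPI1, which encodes PU.1, by 0.64 and 0.68 (adjusted p = 0.0124 and 0.00636), and MYC by 0.75 and 0.90 (adjusted p = 0.0122 and 0.00361). BCL11A fell by 0.57 and 0.65 (adjusted p = 0.028 and 0.011). LMO2, a partner of GATA factors, fell by 0.46 in WT (adjusted p = 0.0139) and stood at -0.30 in L359V, where it did not pass (adjusted p = 0.0503). GFI1B, a repressor of erythroid and megakaryocytic cells, rose by 0.89 in WT (adjusted p = 0.00755) and stood at 0.46 in L359V (adjusted p = 0.0712). In T354M none of the 6 passed, with CEBPA at -0.29, SPI1 at -0.16, MYC at -0.08 and GFI1B at 0.56. Of the 6, CEBPA had the largest difference between L359V and WT, -0.61, and it did not pass (adjusted p = 0.0954).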
